A study of Homo sapiens with 12 samples.

How the data were processed

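Splicing was measured by RASL-seq in HEK293T cells, a human embryonic kidney line carrying the SV40 large T antigen. In this assay, pairs of DNA oligos anneal next to each other across a chosen splice junction in total RNA, are joined by a ligase, and are amplified and sequenced. Each read counts 1 ligated oligo pair and therefore 1 isoform of a chosen event. The labels state a panel of 3726 events. The 12 libraries are 11 cell libraries and 1 library made with water in place of RNA. Each group holds 1 library, so no group has a replicate, and the labels name no separate cultures.

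Reads were aligned with Bowtie to hg18, per the submitters' processing notes; the Bowtie version is not given in the sources used here. The authors deposited, for each library, raw counts of reads for the 2 isoforms of every event that had at least 1 read, together with the event's span, gene symbol and class. The deposited counts carry no normalization. The 2 count columns have no header. No source used here says which isoform contains the alternative exon, so every share below is that of the isoform listed first, and a rise of it cannot be read as exon inclusion or exon skipping. Gene symbols are those of the files. Of 2496 symbols, 2379 matched a symbol or a single synonym in a current gene table, which was used for names only. Exon numbers and untranslated regions were not assigned, since no hg18 annotation was used here.

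From these counts the share of the first-listed isoform was computed per event and library, as a percentage of both isoforms' reads. Events with at least 20 reads in each library of a comparison were tested. Exact Clopper-Pearson 95% intervals of shares, and exact Poisson intervals of a gene's reads scaled to library size (counts per 1e6 reads, CPM), cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

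The main test of EGF used the only repeat of a contrast in the design: 2 pairs with and without EGF that share no library. It was edgeR's quasi-likelihood test on the isoform counts, with a term for each library, the isoform, the isoform by pair, and the tested isoform by EGF. Each event had 1 residual degree of freedom, pooled across events, and this residual holds any real difference between the pairs. An event was called at a Benjamini-Hochberg adjusted p under 0.05. The same model tested the SRPK siRNA over both EGF states; there the residual holds the interaction of siRNA and EGF, which has no test of its own. The p-values set each shift against counting error and a spread largely pooled across the events of these libraries. They do not measure each event's own spread between pairs, nor the spread between cultures.

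All other comparisons set 1 library against 1 library. They used a 2-sided Fisher's exact test on the isoform reads with Benjamini-Hochberg adjustment and a shift of at least 10 percentage points. Such a test compares the 2 libraries, not the conditions. To measure how much of the EGF response a library held, events shifted at least 10 points by EGF in 1 pair were taken, and the median shift in the EGF direction was computed in the other set of libraries. Intervals of these medians come from 2000 bootstrap draws over events and cover the choice of events only. The medians were also set among 10000 random lists of the same size matched on mean reads. Gene lists fixed before the data were examined (13 lists) were tested with a one-sided Fisher's exact test of called against tested events, adjusted over the lists.

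The events named follow a rule fixed in advance. For EGF these are the 10 called events with the largest mean rise and the 10 with the largest mean fall that moved the same way in both pairs. For the SRPK siRNA they are the events shifted the same way in both EGF states, since fewer than 10 were called. For each inhibitor they are the 3 largest shifts each way. Called events of the gene lists, or the 2 largest per list between single libraries, were added.

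The tests were tried on simulated counts drawn at the real depths with 200 changed events. For the fits, counts were drawn with 1 dispersion for all events, the common value that edgeR estimated from these data. Such counts match edgeR's pooling and hold no event's own spread between pairs. The false calls below therefore do not measure the error of the fits in the real data. For EGF over 1857 events, edgeR recovered 65 of 100 events changed by 1 log2 unit and 89 of 100 changed by 2 units, with 1 false call. DESeq2 recovered 40 and 72, and limma recovered 0 of either size, while 12.4% of unchanged events had an unadjusted limma p under 0.05. For the SRPK siRNA over 1910 events, edgeR recovered 2 of 100 and 22 of 100, with 0 false calls. The two-library rule, simulated for EGF alone against the DMSO control over 1904 events, recovered 137 of 200 events moved by 20 points, with 1 false call. These draws held counting error only, so that false call does not measure the spread between real libraries. Between the 2 real control libraries 14 of 2220 events passed the rule.

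Alternatives fixed before the data were examined were limma, DESeq2, TMM scaling, other read minimums (1, 10 and 50), other shift sizes (5 and 20 points, or a 2-fold change of the isoform ratio with a pseudocount of 0.5), equal depth, and leaving out events with reads in water. Equal depth means that each cell library was thinned at random to 1329836 reads. It was planned for the two-library comparisons and added for the fits and the EGF response later. Those additions, a background of events with both isoforms for the gene lists, and a combined call with 10 points in both pairs, were chosen after seeing the data. R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scipy 1.17.1, were used.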

Results

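The libraries came from 2 sets of HEK293T cells, 1 set per sequencing lane. In the siRNA set, cells received a control siRNA or siRNA against the SR protein kinases SRPK1 and SRPK2, each without EGF and with EGF at 100 ng/ml. A water library ran beside them. The other set, called the inhibitor set, held a DMSO control, EGF alone at 100 ng/ml, and EGF together with 1 of 5 signaling inhibitors. These were WP1066 (JAK2 and STAT3), wortmannin (phosphatidylinositol 3-kinase), U0126 (MEK), rapamycin (mTOR) and GF109203X (protein kinase C). The labels give 20 nM wortmannin, 10 µM U0126, 100 nM rapamycin, 3 mM WP1066 and 10 mM GF109203X; the last 2 units are printed as the labels state them and could not be checked. The labels name no solvent for EGF alone. Label fields differ for some libraries: K2 and K3 both appear for the SRPK siRNA, WP1067 beside WP1066 and U0127 beside U0126. The labels also give the WP1066 and wortmannin libraries the same barcode sequence. The study asked how EGF signaling through AKT and SRPK reaches splicing.

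The 11 cell libraries held 1329836 to 5021916 reads. The library of control siRNA with EGF (1329836 reads) and that of EGF alone (1411812 reads) were the shallowest. The others held 2805833 reads (WP1066) or more. Across all libraries 3376 events had a read, of which 1798 had at least 20 reads in every cell library. Cassette exons made up 2983 of the events. RPS24, a ribosomal protein gene, had the most reads in each library, from 4.60% of reads in control siRNA cells with EGF to 16.7% with wortmannin. The water library held 447 reads. No group has replicates, so single shares are given with exact 95% intervals that cover counting error only.

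SRPK2, a target of the siRNA, was lower in both libraries labelled SRPK siRNA. It stood at 561 CPM (counts per 1e6 reads, interval 539 to 585) against 1557 (1523 to 1592) with control siRNA, and with EGF at 484 (462 to 507) against 1419 (1356 to 1484). The ratios were 0.361 and 0.341. The inhibitor libraries were also below the DMSO control (1496 CPM), down to 689 with WP1066. SRPK1, the other named target, was not lower: it had 29 reads with SRPK siRNA and 21 with control siRNA, at 7.06 (4.73 to 10.1) and 4.18 (2.59 to 6.39) CPM. The SRPK1 ratio was 1.69 (0.929 to 3.11) without EGF and 1.67 (0.465 to 9.05, on 14 and 3 reads) with EGF, so a fall as large as that of SRPK2 lay outside the counting interval.

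The first comparison asked which splicing events EGF changed. EGF moved the isoform balance of 515 of 1857 tested events, in 485 genes. The share of the first-listed isoform rose in 292 events and fell in 223. THBS3, encoding a thrombospondin of the extracellular matrix, rose by 73.4 points ± 11.4 (SD, n = 2 pairs), and RNF167, encoding a ubiquitin ligase, rose by 60.6 ± 14.1. EIF5, encoding a translation initiation factor, rose by 43.2 ± 0.931. SSBP3, encoding a DNA-binding protein, fell by 53.5 points (SD 15.9), and the casein kinase gene CSNK1D fell by 44.9 (SD 1.28). THBS3 and SSBP3 moved this far only in the 2 libraries with EGF alone, the shallowest. With EGF and WP1066, U0126, rapamycin or GF109203X they averaged 2.94% and 90.8% (4 libraries). The DMSO control had 5.38% and 83.0%. For both, EGF cannot be told apart from something else shared by those 2 libraries. RNF167, EIF5 and CSNK1D stayed nearer EGF alone than the DMSO control in the 4. Of the 515 events, 511 moved the same way in both pairs and 185 moved at least 10 points the same way in both. The median absolute mean shift of called events was 8.44 points.

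The THBS3 event (chromosome 1, 153439721 to 153441474, hg18) had 3.15% of its first-listed isoform in control siRNA cells (interval 0.865 to 7.87, 127 reads). With EGF it had 84.7% (78.9 to 89.3, 202 reads). In the inhibitor set the THBS3 share went from 5.38% to 70.8%, with an edgeR log2 odds of 6.44 ± 0.58 (SE) and an adjusted p of 1.78e-26. The RNF167 cassette exon (chromosome 17, 4784401 to 4785116) went from 15.4% to 85.9% and from 33.6% to 84.3%. The EIF5 cassette exon (chromosome 14, 102870351 to 102871742) went from 9.90% to 53.7% and from 8.13% to 50.7%, at 1009 to 1646 reads per library. The CSNK1D exon (chromosome 17, 77795997 to 77800039) went from 64.5% to 18.7% and from 63.9% to 19.9%. SSBP3 (chromosome 1, 54495448 to 54519698) went from 87.3% to 22.6% and from 83.0% to 40.8%, on 53 to 190 reads.

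The other large rises were in SOCS7 (49.2 points), the mitochondrial protease gene HTRA2 (47.8), C1orf9 (46.2), the kinase gene CAMKK2 (44.2), FBXO38 (42.2), and the RNA-binding protein genes IGF2BP2 (40.2) and RBM15 (39.9). HTRA2 and SOCS7 rest on 21 to 31 reads in the EGF libraries. The other large falls were in MPZL1 (-49.7 points), the chromatin remodeling gene MTA1 (-45.2), PPFIBP1 (-42.4), the RNA helicase gene EIF4A2 (-39.7), INF2 (-37.8), the histone gene H2AFV (-36.0), COL4A3BP (-34.7) and TMEM63B (-34.3). Each of these passed the edgeR test. In the 4 libraries with EGF and WP1066, U0126, rapamycin or GF109203X, RBM15 and MPZL1 averaged 8.43% and 88.3%. The DMSO control had 6.10% and 95.7%. H2AFV, IGF2BP2 and COL4A3BP also lay nearer that control than EGF alone in each of the 4, so the limit given for THBS3 holds for them too. HTRA2, CAMKK2, FBXO38, MTA1, PPFIBP1, INF2 and TMEM63B lay nearer EGF alone. SOCS7, C1orf9 and EIF4A2 were mixed.

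Genes of splicing factors were among the changed. Of the list of hnRNPs and other splicing regulators, 19 of 40 tested events were called (19 adjusted over the list alone), 17 with a rise and 2 with a fall. Outside this list 27.3% of events were called, and the list's one-sided Fisher's exact test gave p = 0.00557, adjusted p = 0.0724 over 13 lists, so it did not pass the correction. Against events with both isoforms present, a background chosen after seeing the data, it was 19 of 27 with adjusted p = 0.0345. SNRNP70, encoding a U1 snRNP protein, rose by 36.1 points ± 2.91 (SD, n = 2 pairs), and RBM10 rose by 29.5. RBM5 moved in 3 events, by 17.4, 14.7 and -23.1 points, and HNRNPH3 rose by 12.8.

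Of the SR protein events, 8 of 15 were called (8 adjusted over the list alone; list test adjusted p = 0.204), 6 with a rise and 2 with a fall. SFRS7 (now SRSF7) rose by 18.9 points, SFRS3 (SRSF3) rose by 16.1 and TRA2A by 14.0, while SFRS12 fell by 26.7 and SFRS10 (TRA2B) fell by 17.3. In the list named SR protein kinases 4 of 11 events were called (6 adjusted over the list alone, one-sided Fisher's exact test adjusted p = 0.789). This list also held HIPK2 and HIPK3, whose action on SR proteins was not examined here. CLK1, HIPK2 and HIPK3 fell by 12.5, 14.6 and 11.1 points, and SRPK2 rose by 2.91. With EGF and WP1066, U0126, rapamycin or GF109203X, SFRS10 and CLK1 averaged 52.3% and 83.4%. The DMSO control had 45.9% and 70.0%, and EGF alone had 23.9% and 58.5%. The limit given for THBS3 therefore holds for SFRS10 and CLK1 too.

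Genes of EGF signaling moved in part. Among EGF receptor genes and adaptors 2 of 5 events were called (2 adjusted over the list alone): SHC1 rose by 24.8 points and GAB1 fell by 20.5. In the MAPK list 8 of 19 were called (8 adjusted over the list alone), 4 each way, with HRAS at 26.3 points and ELK1 at 8.61. In the PI3K, AKT and mTOR list 1 of 10 was called (1 adjusted over the list alone), EIF4G1 at 5.58 points. In the JAK, STAT and protein kinase C list 0 of 3 were called. None of these lists passed the list test; their adjusted p were 0.789, 0.435, 1 and 1.

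Adhesion and cytoskeleton genes had 24 of 70 events called (24 adjusted over the list alone), 11 with a rise and 13 with a fall. NUMB rose by 33.5 points in 1 event and FGFR1 rose by 28.8, while NCAM1 fell by 25.7. EPB41 rose by 25.7 in 1 event and fell by 10.7 in another. Nuclear receptors and coregulators had 4 of 9 called (4 adjusted over the list alone), with NCOR1 at -17.5 points. Apoptosis genes had 4 of 19 (3 adjusted over the list alone), with CASP8 at 13.2 points. Cell cycle and DNA repair genes had 4 of 22 (4 adjusted over the list alone), with BRCA1 at -11.7 points. Ion channels and transporters had 1 of 6 (0 adjusted over the list alone). Of genes high in HeLa cells, kept as a marker list of another line, 1 event was tested and 0 were called. The adjusted p of these lists were 0.435, 0.572, 1, 1, 1 and 1.

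These counts depend on the test. With limma 0 events passed (smallest adjusted p 0.0631, 761 at an unadjusted p under 0.05), against 645 at an unadjusted p under 0.05 by edgeR, and DESeq2 called 383. TMM scaling of the isoform columns moved the median log2 odds of all events from 0.09 to -0.37 and changed the split to 172 rises and 375 falls (31.4% rises, against 56.7%), so the balance of rises and falls depends on the scaling.

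**Figure D1:**
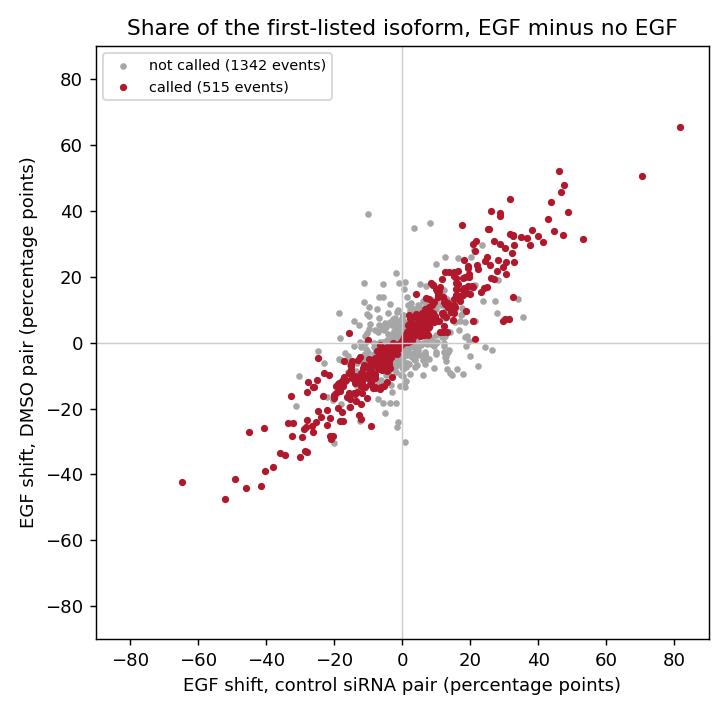
Shift of the first-listed isoform's share with EGF, in percentage points, in the control siRNA pair (x axis) and in the DMSO pair (y axis); each point is 1 of 1857 events, red where called. Most called events lie in the lower left and upper right, with 511 of 515 moving the same way in both pairs.

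The 2 EGF pairs were compared directly. Of 224 events that moved at least 10 points in both, 222 moved the same way (99.1%, interval 96.8 to 99.9). Pearson's r of the shifts was 0.829 and Spearman's rho 0.649 across 1857 events, which are not independent replicates; the pairs share no library. By the two-library rule 261 of 1912 events shifted in control siRNA cells (140 up, 121 down) and 221 of 1904 in the inhibitor set (121 up, 100 down). Between the 2 control libraries 14 of 2220 events differed by that rule, and between the 2 EGF libraries 5 of 1874.

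The next comparison asked whether EGF acted when SRPK was targeted. With SRPK siRNA, EGF shifted 34 of 2203 events (24 up, 10 down), and 7 with all libraries thinned to equal depth, where EGF in control siRNA cells shifted 217. Over the 302 events chosen on the inhibitor set, the median shift in the EGF direction was 15.95 points (interval 14.5 to 17.5) in control siRNA cells and 0.061 points (-0.607 to 0.859) in SRPK siRNA cells, or 0.383% of the former (-3.73 to 5.42). EGF moved 152 of the 302 events in the EGF direction in SRPK siRNA cells and 286 in control siRNA cells. SNRNP70 was at 85.0% without and 80.4% with EGF, and CSNK1D at 8.71% and 11.6%. Among listed genes, the shifts by EGF in these cells were BCL2L1 (29.0 points), the kinase gene CLK2 (27.9) and the checkpoint kinase gene CHEK2 (17.9). The difference between the EGF effects in the 2 siRNA arms has no replicate test.

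The same library without EGF did not lie at the control. Over the 302 events, SRPK siRNA alone moved the share by 12.4 points in the EGF direction (11.2 to 14.2), 77.8% of the EGF shift (69.5 to 87.4), and 269 events moved that way. SRPK siRNA with EGF stood 12.1 points (11.1 to 14.5) from control siRNA without EGF. Against control siRNA with EGF it stood at -2.56 points (-3.45 to -1.17). RNF167 was at 72.0% with SRPK siRNA alone, EIF5 at 37.0% and RBM10 at 28.3%, against 15.4%, 9.90% and 3.30% with control siRNA. THBS3 and SSBP3 were at 10.6% and 84.7%. Medians of the 10000 random lists for SRPK siRNA alone ran from 0.0 to 1.02 points. Such lists set a low bar, since even the 0.061 points of EGF in SRPK siRNA cells lay above all of their own.

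The siRNA itself was then compared in each EGF state. Without EGF, 288 of 2233 events shifted (164 up, 124 down), and with EGF 74 of 1918 (44 up, 30 down). At equal depth these counts were 175 and 52. Without EGF the SR protein genes TRA2A (in an event other than the one called for EGF) and SFRS3 shifted by 32.1 and 31.6 points, HNRNPL by 47.1, SNRNP70 by 41.8, HRAS by 26.7, HTRA2 by 37.7, NCAM1 by -35.4 and the apoptosis gene BAX by 62.6 on 45 to 56 reads. Of the SR protein events 4 of 17 shifted without EGF (4 adjusted over the list alone), against 12.8% of events outside the list, and the list did not pass its test (adjusted p = 0.841). With EGF, 5 of 16 SR protein events shifted (5 adjusted over the list alone; 4 up, 1 down), more than outside the list by a one-sided Fisher's exact test (adjusted p = 0.00304, between 2 libraries). TRA2A shifted by 23.2 and SFRS6 by -31.1 points. SFRS6 rests on few reads, with 55 over the gene for control siRNA with EGF and 23 for SRPK siRNA with EGF.

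Over both EGF states 16 events shifted the same way, 7 up and 9 down, and 11 shifted in opposite ways. PIP5K1A, a phosphoinositide kinase gene (chromosome 1, 149479140 to 149481537), shifted most among the rises, by 40.0 points without and 54.1 with EGF. The other rises were TRA2A (32.1 and 23.2), PDDC1 (19.8 and 17.1), FAM76B (28.4 and 13.1), SFRS3 (31.6 and 12.3), NFYA (13.1 and 11.4) and C1orf43 (10.2 and 14.7). The falls included the adhesion receptor genes EMR2 (-49.4 and -22.4) and CD97, the latter in 2 events (-46.7 and -15.9, and -26.5 and -16.6). RBM23 (-15.7 and -31.8), NFAT5 (-32.7 and -11.8), BCL11A, GSK3B, DPF2 and IVNS1ABP had falls of 11.6 points or more in each state. By edgeR over both states 0 of 1910 events passed, with 101 at an unadjusted p under 0.05 and a smallest adjusted p of 0.238. DESeq2 called 1 event and limma 0. In simulated data that test found 22 of 100 events changed by 2 log2 units, so it could have missed most.

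The last comparisons asked which inhibitor changed the EGF response. Over 322 events chosen on the siRNA set, EGF alone moved the share by a median of 13.3 points (12.1 to 15.2) from the DMSO control. With wortmannin the median was 0.918 points (0.185 to 1.98), 6.88% of EGF alone (1.40 to 14.4). With WP1066 it was 12.5 points (93.8%, 80.7 to 109), with U0126 11.8 (88.4%, 75.7 to 99.9), with rapamycin 11.9 (89.2%, 75.1 to 103) and with GF109203X 12.5 (93.9%, 83.4 to 109). The inhibitors have different targets and doses, and no library had an inhibitor without EGF. All 6 medians share the DMSO control, and differences between them have no replicate test. Because the WP1066 and wortmannin labels carry the same barcode sequence, an exchange of these labels cannot be told apart. The values are given by the labels as they stand.

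**Figure D2:**
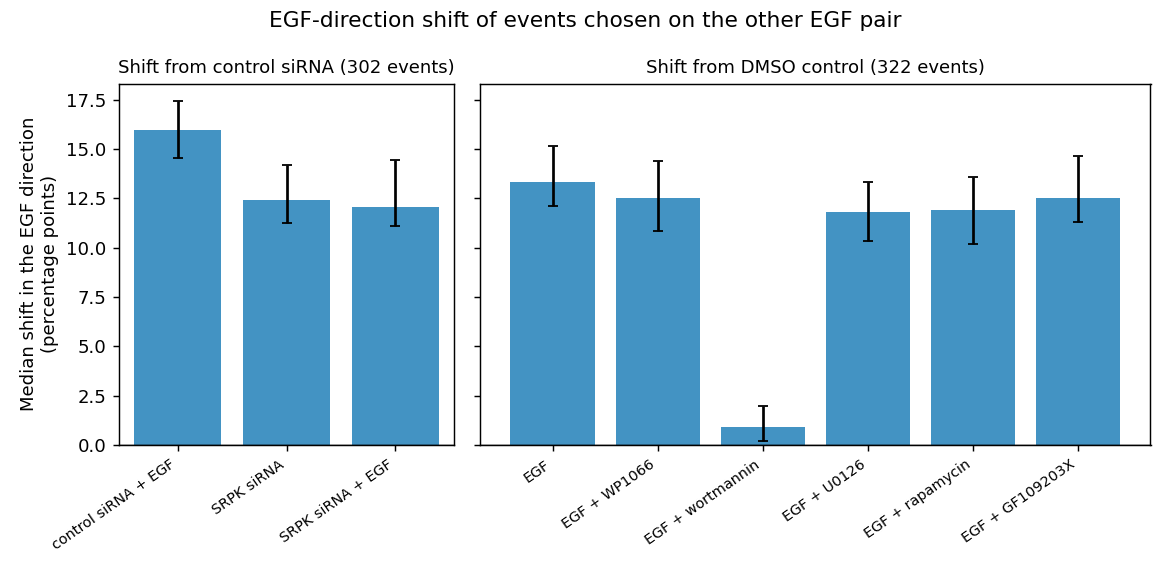
Median shift in the EGF direction, in percentage points, over 302 events in the siRNA set (left, from control siRNA) and 322 events in the other set (right, from the DMSO control); bars are 1 library each and error bars are 95% bootstrap intervals over events. SRPK siRNA without EGF stands at 12.4 points, and EGF with wortmannin at 0.918, below the other inhibitors.

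Against EGF alone, wortmannin shifted 222 of 1902 events (73 up, 149 down). EIF4A2 went from 23.4% to 75.4%, past its 62.3% in the DMSO control, and SNRNP70 went from 81.6% to 14.5%, below its 47.6% in that control. The ceramide transporter gene COL4A3BP shifted by 38.3 points, SSBP3 by 46.9, THBS3 by -69.8 and ASXL3 by -56.5. Among listed genes, STAT3 shifted by 30.2, TSC2 by 32.1, SHC1 by -25.2, HTRA2 by -48.2 and FGFR1 by -26.1 points. RBM10 was at 6.35% and EIF5 at 13.3%, near the control. CSNK1D stayed near EGF alone, at 23.7%. Against the DMSO control, wortmannin with EGF shifted 124 of 2126 events.

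The other inhibitors shifted fewer events against EGF alone: 88 of 1848 with WP1066, 93 of 1882 with U0126, 80 of 1886 with rapamycin and 89 of 1893 with GF109203X. THBS3 had the largest drop in each, at -70.8, -68.3, -68.4 and -63.8 points, and SSBP3 shifted by 44.6, 57.9, 49.8 and 47.8. Other leading events were NEO1 (45.3), ASPM (37.5), CCDC66 (-57.2) and RBM15 (-30.8) with WP1066. With U0126 they were MPZL1 (45.8), ASPM (32.3), CCDC66 (-61.7) and ATL2 (-40.0). With rapamycin they were MPZL1 (42.1), BRD8 (37.0), CCDC66 (-46.4) and SOCS7 (-40.8), and with GF109203X MBD1 (37.2), MPZL1 (36.0), RNF14 (-31.4) and IGF2BP2 (-31.3). SFRS10 (TRA2B) and CLK1, encoding an SR protein and a kinase of SR proteins, shifted up under each of the 4. For SFRS10 the shifts were 27.5, 15.9, 34.5 and 35.6 points, and for CLK1 28.4, 25.8, 24.5 and 21.0. Of the SR protein events 4 of 16, 3 of 16, 3 of 17 and 4 of 16 shifted, each of them up (4, 3, 4 and 4 adjusted over the list alone), and with wortmannin 4 of 16 (1 up, 3 down). The list did not pass its test in any of these (adjusted p = 0.0732, 0.533, 0.423, 0.0700 and 0.693). TRA2A and SFRS3, shifted by the SRPK siRNA in both EGF states, were also above EGF alone in the 4, at means of 66.4% and 85.0%, so such shifts from a library with EGF alone are not particular to the siRNA.

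Of the events shifted by each inhibitor against EGF alone, 29 to 54 were shared in direction between any 2 inhibitors, among 1828 events. Independent lists would share 1.77 to 5.68. Simulated unchanged libraries shared 0.0 on average over 20 draws. They held counting error only, so hardly any event could pass, and this value does not measure overlap through a shared library. All comparisons use the same EGF library, which cannot be split, so part of the excess may come from it.

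**Figure D3:**
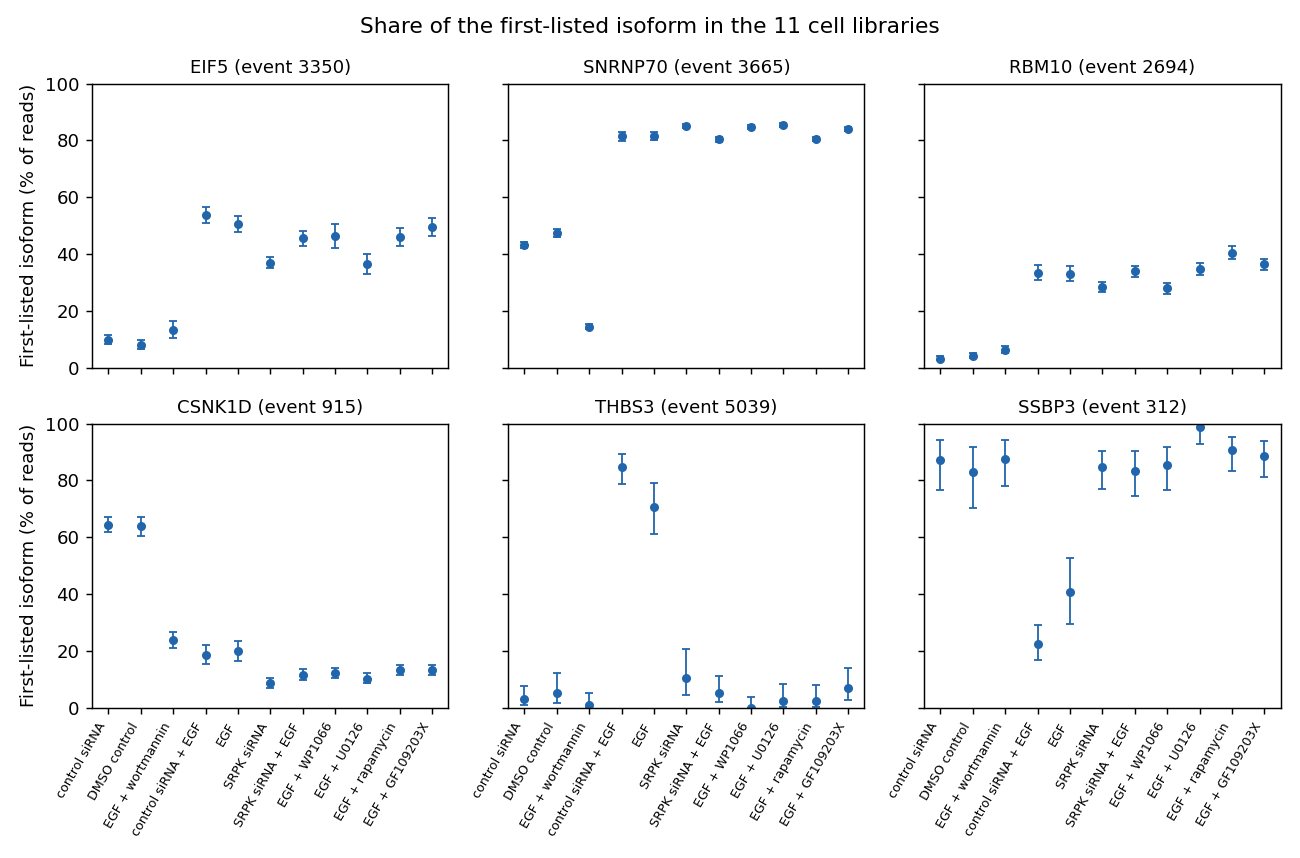
Share of the first-listed isoform (percent of the event's reads, y axis) in the 11 cell libraries (x axis) for 6 events; points are single libraries and bars exact 95% intervals. EIF5, SNRNP70 and RBM10 separate the controls and wortmannin from the rest, CSNK1D is low in every library but the controls, and THBS3 and SSBP3 stand apart in the 2 libraries with EGF alone.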

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

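The tests of explanations in this part were chosen after the results had been seen. FOXRED1, FAM135A and MTMR3 moved in opposite ways with EGF in the 2 siRNA arms, which drew attention to them; each arm is 1 library per state and the difference was not tested. The EGF shift was 37.8 points higher with SRPK siRNA for FOXRED1 (event on chromosome 11, -15.0 with control siRNA and 22.8 with SRPK siRNA). It was 41.7 points higher for FAM135A (-22.0 and 19.7) and differed by -50.5 points for MTMR3 (31.7 and -18.8). FOXRED1 without EGF was already at 37.4% with SRPK siRNA, against 83.5% with control siRNA.

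The water library held 447 reads where no RNA was added, and no comparison uses it. They spread over 268 events, with 26 reads in the largest, and made up 0.00315% of the lane's reads. Leaving out the events with reads in water gave 380 EGF calls, all of them among the 515.

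The library with SRPK siRNA and no EGF held most of the EGF shift. An exchange of labels between the 2 SRPK siRNA libraries would not remove this pattern, since their medians were 12.4 and 12.1 points. Whether their labels were exchanged cannot be told from such similar values. Over the same 302 events the DMSO control lay -0.044 points (interval -0.529 to 0.446) from control siRNA. It is shallower than the SRPK siRNA library without EGF. These events were chosen for a shift between that control and EGF, which holds that control away from the EGF direction. The value therefore cannot decide whether depth accounts for the shift of the SRPK siRNA library without EGF. Whether that library holds a knockdown cannot be told apart from the spread between libraries: its SRPK2 ratio was 0.361 (0.344 to 0.378), while the 7 libraries with EGF and no SRPK siRNA put the lower limit for a further library at 0.366; with EGF the SRPK siRNA library was at 0.341 (0.320 to 0.364), and SRPK1 was not lower in either. Whether loss of SRPK moves these events, or something else in that library did, cannot be told apart from 1 library, whose value was 77.8%.

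With wortmannin and EGF, 61 of the 322 EGF-shifted events lay at least 10 points in the EGF direction and 34 in the opposite one. By the median over these events, the library with wortmannin and EGF lay near the control. The labels give it and the WP1066 library the same barcode sequence, and pooled reads would make them alike. Their RMS difference was 9.60 points, against 4.38 between the 2 EGF libraries and 9.08 to 9.86 between wortmannin and the other 3 inhibitors. This argues against full pooling, while the size of any mixed part was not estimated. The wortmannin library was no copy of the control library, since 124 events differed against 14 between the 2 controls. An exchange of the WP1066 and wortmannin labels cannot be told apart, since no measured gene marks either drug; the library labelled WP1066 held 93.8% of the EGF shift.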

How the results depend on the processing

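The equal-depth values for the EGF and siRNA fits and the EGF response, and the combined call, were chosen after seeing the data. EGF over both pairs gave 0 calls with limma, which also found none of the simulated changes. Those counts were drawn with 1 dispersion for all events, so they do not decide between limma and edgeR here. The two-library rule, which leaves out 1 pair, gave 221 to 261, and calls with 10 points in both pairs came to 185 by construction. The other settings gave 380 to 547 calls. The SRPK siRNA fit gave 1 call with DESeq2 and 0 otherwise. Requiring 20 points cut the two-library counts to 117 and 104 (EGF with control siRNA and in the inhibitor set), 11 (EGF with SRPK siRNA), 117 and 25 (siRNA without and with EGF), 35 (WP1066), 116 (wortmannin), 26 (U0126), 32 (rapamycin) and 35 (GF109203X). Requiring 5 points gave 70 (EGF with SRPK siRNA), 128 (siRNA with EGF), 147 (WP1066), 154 (U0126), 139 (rapamycin) and 165 (GF109203X). A 2-fold ratio change gave 412 and 332 (EGF with control siRNA and in the inhibitor set), 439 (siRNA without EGF) and 345 (wortmannin). At equal depth EGF with SRPK siRNA gave 7 events and the siRNA without EGF 175; fewer reads lower the power of the exact test. Agreement of the EGF pairs was 93.6% from 5 points, and 67.7% over the 1597 tested events whose share changed at all in either pair. The EGF response in each library stayed within its interval under every alternative: -1.94% to 2.99% with SRPK siRNA, 72.7% to 84.1% for the siRNA alone, and 3.84% to 12.5% with wortmannin. TMM turned the log2 odds of HNRPDL (0.50 to -0.021) and CTTN (0.35 to -0.17) along with a shift common to all events, whose median went from 0.09 to -0.37. Of the named EGF events, 81 stayed called with TMM and 15 did not; with DESeq2 71 did and 27 did not, and with limma all 98 lost the call. Depth limits the 2 EGF-alone libraries most.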

Other observations

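The reads per event also give rough gene levels, which no comparison above uses. The genes here were chosen after their values were seen, and each value is 1 library. Over 1688 genes with at least 100 reads in the 4 libraries of the EGF pairs, 110 were at least 2-fold higher with EGF in both pairs and 90 at least 2-fold lower, with 0 in opposite ways. TMM scaling lowers every log2 ratio by 0.13 in the siRNA pair and 0.08 in the DMSO pair. FOSB, an immediate early gene, was 28.0-fold (interval 17.3 to 47.9) and 27.4-fold (13.9 to 61.5) higher. NAB2 was 6.50-fold and 5.03-fold higher, the survival gene MCL1 3.81-fold and 4.69-fold, and the cyclin gene CCNL1 4.05-fold and 3.94-fold. The SR protein gene SFRS2 was 5.40-fold and 4.96-fold higher, and SFRS7 3.93-fold and 3.55-fold. SAT1, of polyamine catabolism, was at 0.129 and 0.135 of its control level, and the asparagine synthetase gene ASNS at 0.243 and 0.283.

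These genes did not follow 1 pattern in the other libraries. SAT1 stood at a log2 ratio of -3.07 with SRPK siRNA alone and at -0.47 with wortmannin and EGF, and SFRS2 at 2.25 and 0.26. CCNL1 was at 0.18 with SRPK siRNA alone and at -0.69 to -0.04 in the 5 inhibitor libraries. HNRNPC had 1049.8 times its control CPM in the siRNA pair (187 to 41613, on 1 control read) and 132 times in the DMSO pair (35.6 to 1100), against 0.0 to 3.21 CPM in the other libraries with an inhibitor or SRPK siRNA.

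In the 4 libraries with WP1066, U0126, rapamycin or GF109203X, 30 events all shifted the same way from EGF alone by the two-library rule. These 30 events had at least 20 reads in every cell library. THBS3 led them, at 70.8% with EGF alone and a mean of 2.94% in the 4, and was near the 4 in both controls (3.15% and 5.38%). BRD8 was at 20.8% with EGF alone and 54.5% in the 4, but at 21.2% to 23.5% in the other libraries, so there the 4 stand apart. Over the 30 events the median difference from the 4, in the direction of EGF alone, was 8.58 points in the DMSO control, 7.04 with SRPK siRNA and EGF, and 13.3 with wortmannin (22 of 30 events toward EGF alone).

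The tests of explanations in this part were chosen after the results had been seen. For these 30 events, chance values of the shared EGF library do not account for the difference, since the control siRNA library with EGF lay on the same side at 100.0% of the events (interval 88.4 to 100.0). Depth cannot be told apart, since both libraries with EGF alone are the shallowest; the 21.3 points at equal depth decide nothing, because random thinning leaves that library as it is and only adds noise to the shares of the 4. Whether each inhibitor moves these events, or something else in the handling of those cells does, cannot be told apart, since the labels name no solvent for EGF alone and the wortmannin library lies between; the median difference of the control siRNA library with EGF, 21.8 points, would be the same.

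The 2 control libraries differed by an RMS of 3.45 points and the 2 EGF libraries by 4.38 points, against 9.21 points between the DMSO control and EGF alone.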
